A study of Mus musculus with 12 samples.

How the data were processed

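Bulk RNA sequencing was analysed for 12 libraries of liver and tumor from mice with orthotopic Fo5 tumors, taken 24 h after 1 intravenous dose of vehicle or of 5 mg/kg of the anti-HER2/CD3 antibody. Mice entered treatment when tumor volumes averaged 350 to 500 mm3, per the labels' protocols. Total RNA was extracted with a column kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Tissue and treatment of each library were taken from its title, and the groups are liver vehicle, liver TDB, tumor vehicle and tumor TDB with 3 libraries each. The title numbers libraries 1 to 3 within each group and does not say that a number marks one mouse across tissues. The series' design text names 3 mice per treatment, so p-values of single genes measure the spread between mice. By that text the liver and tumor values come from the same mice. As no label ties library numbers to mice across tissues, the main interaction test treats the 12 libraries as unpaired.

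The deposited count table holds whole-number counts for 52636 Ensembl gene identifiers, not normalized, with one column per library. GSNAP, limma and the genome build GRCm38 are named, without version or role, per the submitters' processing notes. The read counter, the annotation release, the strand setting and any filter are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart, and genes of near-identical families (Gbp, Tgtp, Saa, H2 and others) are uncertain. The authors also deposited FPKM values. In that table the factor of each library equals the median-of-ratios size factor of the counts (largest relative difference 1.1e-15), and the gene factor lies within 1% of the genomic span, introns included, for 84.3% of 10262 genes checked and within 1% of the exonic length for 0.9%. These FPKM values therefore understate long-intron genes relative to others and were used only as an alternative, as log2 of the value plus 1 or 0.1, a scale that understates changes of low genes. Symbols and positions came from GENCODE release M21 on GRCm38, which matched 52403 identifiers. The 233 others held 0.0118% to 0.0192% of the counts of a library and stayed in the tests. Of the identifiers, 24841 had 0 counts in each library, and 73 symbols belonged to more than one identifier. No pair of libraries within a group agreed within sampling noise.

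Depth was 18460159 to 29396324 counts per library. Intervals of count ratios (95%, exact conditional binomial) and lower bounds against a group without counts (a floor of 3 counts over the group) cover counting error only.

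Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, genes kept by filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fit, quasi-likelihood F test). P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05 and no fold minimum. TDB was compared with vehicle within liver (6 libraries) and within tumor (6 libraries), and the difference of both effects was tested as an interaction over the 12 libraries with 4 group means. Calls shared by liver and tumor were counted among genes tested in both, per direction, with a one-sided Fisher's exact test. These comparisons, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, except where a choice is said to be later.

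The 17 gene lists were interferon-gamma response, type I interferon-stimulated genes, MHC class I antigen processing, MHC class II presentation, T cell activation and cytotoxicity, lymphocyte homing receptors, endothelial adhesion molecules, other chemokines, inflammatory cytokines and NF-kB targets, acute phase, cytochrome P450 and bile acid synthesis, lipid and glucose metabolism, coagulation and endothelial hemostasis, angiogenesis and tip endothelium, proliferation, p53 targets and apoptosis, and immediate early and heat shock genes. The 16 marker lists covered T, NK and B cells, neutrophils, monocytes and macrophages, Kupffer cells, dendritic cells, pan-endothelial and liver sinusoidal endothelial cells, hepatocytes, cholangiocytes, fibroblasts with stellate cells and pericytes, mammary tumor epithelium, adipocytes, skeletal muscle and erythroid cells. Of 540 listed symbols 1 was not in the annotation. Lists with at least 5 measured members were tested with limma 3.58.1 (cameraPR on signed z scores of the edgeR p-values, preset correlation of 0.01) and adjusted over lists within each comparison. With this preset value the test takes a list's genes as nearly independent units, so its p-values do not measure the spread between mice. Tests with an estimated correlation (camera) and rotation tests (fry) were alternatives. Directional fry asks whether a list's genes move one way on balance, mixed fry whether they change either way, and neither compares the list with other genes. Ranges and counts of alternatives given for a single list include these tests. Those given for a single list or gene leave out the alternatives that change only the threshold, while totals over many lists or genes include them. With the preset correlation 17 of 30 tested lists passed in liver, 19 of 28 in tumor and 18 of 31 in the interaction, with an estimated correlation 2, 2 and 11, by directional fry 12, 20 and 17 and by mixed fry 17, 25 and 23. The 2 in each tissue were the interferon-gamma response and the MHC class I lists.

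Genes were named by rule. For each tissue these were the 10 highest and 10 lowest log2 fold changes among called genes whose 3 TDB values lay on one side of the 3 vehicle values (which chance gives for 10% of genes) with at least 5 CPM in the higher group. Predicted genes, immunoglobulin and T cell receptor segments, and pseudogenes with a symbol ending in -ps or -ps and a number were left out. Pseudogenes under other symbols were not left out. Up to 4 members with the smallest p of each list were added, as were Vcam1, Icam1, Sele, Selp, Pecam1, Cxcl9, Cxcl10, Ifng, Gzmb, Cd3e, Cd8a, Cd4, Erbb2, Saa1 and Cyp7a1. For the interaction the 10 highest and 10 lowest called genes with at least 5 CPM in a group were taken, without the condition on separation, with the same fixed genes. The text names a part of these, and 1 gene that the rule names is not reported here. CPM values are relative to TMM library sizes within a tissue, except in the comparison of levels between tissues, which scaled all 12 libraries together.

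Each test was tested on simulated data with the real libraries' means and sizes and 200 changed genes. At 2-fold and 4-fold, edgeR recovered 3 and 63 of 100 changed genes each in the liver comparison (13499 genes, 2 unchanged genes called), 71 and 96 in tumor (15291 genes, 11 called) and 4 and 46 in the interaction (16373 genes, 5 called). DESeq2 recovered 20 and 80, 72 and 97, and 12 and 62, with 35, 39 and 21 unchanged genes called. Simulated genes were drawn independently, without a trend of a library on transcript length and GC content. These counts therefore do not cover the effect of such a trend in liver.

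The alternatives were size factors by median of ratios, upper quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on the FPKM values, a log2 fold change of at least 1, an adjusted p under 0.01, one fit of the 12 libraries, blocks by library number or mouse, and each library left out in turn. A trend of each library on transcript length and GC content, removed as an offset (splines with 5 degrees of freedom), was added after seeing the data, also without liver TDB 3 and with the block. Splits of the libraries into other groups of 3 were counted in full within a tissue (10 splits) and drawn 100 times with a fixed seed for the interaction and the overlap.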

Results

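RNA was sequenced from dissociated liver and dissociated tumor of female FVB/NJ mice with Fo5 tumors, a mammary tumor of an MMTV-HER2 transgenic founder line grown in the mammary fat pad. Mice received 1 intravenous dose of vehicle or of 5 mg/kg of a T cell-dependent bispecific antibody (TDB), which binds HER2 on tumor cells with one arm and CD3 of the T cell receptor complex with the other. Organs were taken 24 h later. The 12 libraries form 4 groups of 3 (liver vehicle, liver TDB, tumor vehicle and tumor TDB), and the series' design text gives 3 mice per treatment for both tissues. Total gene counts were 18460159 to 25542980 per liver library and 20796764 to 29396324 per tumor library. Albumin (Alb) took 7.96% to 14.3% of the counts of each liver library, and the milk protein gene Csn3 took 1.83% to 2.21% of those of each tumor library. Levels are given as counts scaled to library size (CPM), mean ± SD with n = 3 mice per group, and log2 fold changes with their standard error (SE).

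The first comparison asked which genes differed in liver between mice given the antibody and mice given vehicle. Genes of the interferon-gamma response rose. Igtp, an interferon-induced GTPase (ENSMUSG00000078853, chromosome 11, 58199556 to 58207591 in GRCm38), went from 69 ± 8.96 to 1300 ± 155 CPM, a log2 fold change of 4.24 (SE 0.23, adjusted p = 0.00098). Tap1, the peptide transporter of antigen presentation, went from 16.7 ± 0.253 to 129 ± 18.8 CPM. In total 70 genes were higher and 3 were lower with TDB among 13657 tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1105 genes had an unadjusted p under 0.05.

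Of 21 measured members of the interferon-gamma response list, 17 rose and 4 did not pass, and 21 rose when adjusted over the list alone. The list's median log2 fold change was 3.66 (camera adjusted p = 7.7e-49, and adjusted p = 0.019 with an estimated correlation). Tgtp1, a GTPase of this list, rose by 7.72 on the log2 scale (SE 0.47), and Gbp2, a guanylate-binding protein, by 5.47 (SE 0.37). Both belong to families of near-identical genes, so the split of reads between family members is uncertain. The chemokine Cxcl9, a ligand of Cxcr3, a chemokine receptor found on T cells, went from 15.1 ± 4.43 to 513 ± 386 CPM (log2 fold change 5.08, SE 0.6, adjusted p = 0.018). Cxcl10, another such ligand, rose by 3.8 (SE 0.35). Ifng itself was too low to test in liver, with 3 counts over the vehicle libraries and 12 over the TDB libraries, a count ratio of 3.32 with a counting interval of 0.897 to 18.3. Of the 12 counts 10 came from liver TDB 2, so the ratio rests on 1 library.

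Of 20 type I interferon-stimulated genes, 4 rose over all genes and 19 adjusted over the list alone, with a median log2 fold change of 1.95 (adjusted p = 4e-23, and adjusted p = 0.063 with an estimated correlation). Ifit1, an antiviral RNA-binding protein, rose by 2.74 (SE 0.33) and Rtp4 by 2.2 (SE 0.3). Of 14 MHC class I antigen processing genes, 5 rose and 13 adjusted over the list alone, with a median of 1.61 (adjusted p = 6.1e-19, and adjusted p = 0.019 with an estimated correlation). They included Tap1 (log2 fold change 2.95, SE 0.21) and the immunoproteasome subunit Psmb9 (2.87, SE 0.34). Of 11 MHC class II presentation genes, 0 passed over all genes by edgeR, against 9 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma-voom. Adjusted over the list alone, 9 of them passed, and their median was 1.18 (adjusted p = 1e-09, and adjusted p = 0.16 with an estimated correlation). Ciita, the class II transactivator, had a log2 fold change of 2.57 (SE 0.56, adjusted p = 0.15).

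T cell markers shifted upward as a list, with a median log2 fold change of 0.98 over 18 genes (adjusted p = 3.5e-11, and adjusted p = 0.054 with an estimated correlation). Cd8a, the coreceptor of cytotoxic T cells, was the 1 member that rose over all genes, from 0.36 ± 0.166 to 2.86 ± 0.921 CPM (log2 fold change 2.98, SE 0.44, adjusted p = 0.043), and 12 rose adjusted over the list alone. Cd3e, a subunit of the T cell receptor complex, was at 1.61 ± 0.564 and 2.59 ± 0.57 CPM (adjusted p = 0.72), and Cd4 had an adjusted p of 0.64. Of 11 T cell activation and cytotoxicity genes, 0 passed by edgeR, 2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom and 1 adjusted over the list alone. Their median was 0.91 (adjusted p = 3.4e-05, and adjusted p = 0.16 with an estimated correlation). Gzmb, a protease of cytotoxic granules, had a log2 fold change of 0.36 (SE 0.44, adjusted p = 0.85). Of 14 lymphocyte homing receptors, 0 passed by edgeR, 8 at an unadjusted p under 0.05, 6 by DESeq2, 0 by limma-voom and 8 adjusted over the list alone, with a median of 0.96 (adjusted p = 5.6e-05, and adjusted p = 0.16 with an estimated correlation).

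Dendritic cell markers had a median of 0.84 over 7 genes (adjusted p = 0.00035, and adjusted p = 0.16 with an estimated correlation), 2 of which rose adjusted over the list alone. Clec9a, a receptor of cross-presenting dendritic cells, had a log2 fold change of 3.75 (SE 0.61, adjusted p = 0.057, with 0.036 and 0.041 without liver TDB 1 and 3 and a range of 1.3e-05 to 0.31 over the alternatives). Monocyte and macrophage markers had a median of 0.31 over 15 genes (adjusted p = 0.0016, and adjusted p = 0.16 with an estimated correlation), 3 rising adjusted over the list alone. Over all genes edgeR passed 0 of these dendritic and 0 of these macrophage markers, limma-voom 0 and 0, DESeq2 1 and 3, and an unadjusted p under 0.05 was met by 4 and 6. Among 8 Kupffer cell markers, Marco, a scavenger receptor of macrophages, rose from 13.6 ± 3.73 to 91.5 ± 46.2 CPM (adjusted p = 0.043), and 2 rose and 1 fell adjusted over the list alone. The list's median was -0.35, its mean 0.16 and its test directed down (adjusted p = 0.75). B cell markers (median -0.1 over 8, adjusted p = 0.15) and neutrophil markers (median 0.36 over 6, adjusted p = 0.39, with 0.037 without liver vehicle 3 and up to 0.95) did not pass, and NK cell markers (median 1.07) had 3 measured members and were not tested.

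Endothelial adhesion molecules, through which lymphocytes leave the blood, did not pass in liver as a list (median 0.09 over 11 genes, adjusted p = 0.11). Of these 0 rose by edgeR, 3 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom and 2 adjusted over the list alone. Vcam1 went from 6.12 ± 0.593 to 21.9 ± 11.1 CPM (adjusted p = 0.13) and Icam1 from 21.7 ± 3.07 to 51.7 ± 9.92 CPM (adjusted p = 0.091). Selp had a log2 fold change of -0.35 (SE 0.35), Pecam1 one of 0.26 (SE 0.24), and Sele, with 9 and 15 counts per group, was too low to test. Without liver TDB 3 the adjusted p was 0.036 for Vcam1 and 0.046 for Icam1, and without liver TDB 1 it was 0.046 for Vcam1; over all alternatives it ranged from 0.00059 to 0.58 and from 0.00042 to 0.55. Pan-endothelial markers had a median of 0.14, a mean of -0.03 and a test directed down (18 genes, adjusted p = 0.3). Liver sinusoidal endothelial markers had a median of -0.09 over 16 genes (adjusted p = 0.28, with 0.031 without liver vehicle 2 and up to 0.75 over the alternatives). Coagulation and endothelial hemostasis genes had a median of 0.33 over 14 (adjusted p = 0.051, with 0.047 without liver vehicle 3, 0.015 without liver TDB 1 and 0.013 to 0.54 over the alternatives), and angiogenesis and tip endothelium genes a median of -0.02 over 10 (adjusted p = 0.55).

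Inflammatory cytokines and NF-kB targets had a median of 0.62 over 16 genes (adjusted p = 3.5e-05, and adjusted p = 0.23 with an estimated correlation), with 2 rising adjusted over the list alone. Socs3, a feedback inhibitor of cytokine signaling, had a log2 fold change of 1.43 (SE 0.24, adjusted p = 0.063, with 0.031 without liver TDB 3 and a range of 2.5e-05 to 0.42). Chemokines outside the interferon-gamma list had a median of 0.33 over 12 genes (adjusted p = 0.015, and adjusted p = 0.23 with an estimated correlation), 4 of them rising adjusted over the list alone. Their call was lost without liver TDB 1 (adjusted p = 0.085) or liver TDB 2 (0.053) and held in 16 of 22 alternatives (0.00028 to 0.23). Cxcl1, a neutrophil attractant, had a log2 fold change of 2.39 (SE 0.46, adjusted p = 0.098, with 0.042 without liver TDB 3 and a range of 4.6e-05 to 0.37). The acute-phase list had a median of 0.52 over 31 genes (adjusted p = 2.2e-06, and adjusted p = 0.29 with an estimated correlation), 4 rising adjusted over the list alone, among them Steap4 (2.01, SE 0.38, adjusted p = 0.091 over all genes, with 0.0042 without liver TDB 1 and a range of 1e-04 to 0.48). Saa1, a serum amyloid protein, was at 3490 CPM in liver vehicle 2 and at 41.1 and 60.6 CPM in the other vehicle libraries, and its log2 fold change was -0.67 (SE 1.59, adjusted p = 0.92), or 3.89 without liver vehicle 2. Over all genes edgeR and limma-voom passed 0 members of these lists, while DESeq2 passed 2 cytokine, 3 chemokine and 5 acute-phase genes, and 5, 4 and 11 had an unadjusted p under 0.05.

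With the preset correlation, hepatocyte markers and cytochrome P450 genes shifted down as lists. By directional fry their adjusted p was 0.045 and 0.17. The hepatocyte markers had a median of -0.37 over 21 genes (adjusted p = 1.4e-05, and adjusted p = 0.16 with an estimated correlation), and the cytochrome P450 and bile acid synthesis genes one of -0.22 over 25 (adjusted p = 3e-04, and adjusted p = 0.29 with an estimated correlation). By edgeR 0 members of either list passed over all genes, by limma-voom 0, by DESeq2 0 and 1, and at an unadjusted p under 0.05 4 and 3 were lower. Alb had a log2 fold change of -0.57 (SE 0.2, adjusted p = 0.46), Cyp8b1, the sterol 12-alpha-hydroxylase, one of -0.99 (SE 0.21, adjusted p = 0.14), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, one of -1.37 (SE 0.71, adjusted p = 0.71). Lipid and glucose metabolism genes had a median of 0 and a mean of -0.06 over 22 genes (adjusted p = 0.15), and shifted down without liver TDB 3 (adjusted p = 0.00028, with 0.00017 to 0.66 over the alternatives). The 3 lower genes were Spc25, a kinetochore component (-1.63, SE 0.24), Alas1, the first enzyme of heme synthesis (-1.19, SE 0.19), and Serpina4-ps1, a pseudogene outside the naming rule and chosen after its values were seen (-2.05, SE 0.28, adjusted p = 0.0343).

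Immediate early and heat shock genes had a median of 0.61 over 17 genes (adjusted p = 0.0014, and adjusted p = 0.18 with an estimated correlation). The AP-1 subunit gene Junb rose by 1.56 (SE 0.24) and was the 1 member past the threshold over all genes, with 5 adjusted over the list alone. The p53 targets and apoptosis list had a median of 0.24 over 17 (adjusted p = 0.0025, and adjusted p = 0.24 with an estimated correlation), 2 rising adjusted over the list alone. Erythroid markers had a median of -1.04 over 5 (adjusted p = 0.0037, and adjusted p = 0.39 with an estimated correlation), a call lost without liver vehicle 2 (adjusted p = 0.31) or liver TDB 3 (0.053) and held in 16 of 21 alternatives (3.9e-06 to 0.43). Proliferation genes had a median of 0.05 over 20 with a test directed down (adjusted p = 0.94, and adjusted p = 0.044 by mixed fry). Of these, 0 passed by edgeR and limma-voom, and 2 were higher by DESeq2. At an unadjusted p under 0.05, 4 were higher and 2 lower. Cholangiocyte markers (median -0.32 over 6, adjusted p = 0.11), fibroblast, stellate cell and pericyte markers (-0.15 over 14, adjusted p = 0.22, with 0.016 without liver TDB 3 and up to 0.73) and mammary tumor epithelium markers (0.48 over 12, adjusted p = 0.07, with 0.032 without liver vehicle 1 and a range of 0.011 to 0.24) did not pass. Erbb2, the mouse counterpart of HER2, was at 1.26 ± 0.218 and 1.48 ± 0.74 CPM in liver. Lpl, lipoprotein lipase, rose by 1.41 (SE 0.22) among 4 adipocyte markers, which like the 1 measured skeletal muscle marker (-0.32) were too few for a list test.

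The liver libraries differed among themselves more than the tumor libraries did, with a common biological coefficient of variation of 32.3% against 13%. Liver TDB 3 lay at 87 on a first principal component with 57.7% of the variance, and the other 5 libraries lay between -53.6 and 5.9. Its deviation from its group mean correlated with transcript length across genes (Spearman 0.7, across genes, which are not independent replicates), and mitochondrial genes took 2.05% of its counts. Without it, 151 genes were higher and 12 lower. Without liver vehicle 1, 2 or 3 or liver TDB 2 in turn, 18, 14, 17 and 24 genes were higher, and 0 were lower by edgeR, against 163, 242, 255 and 175 lower at an unadjusted p under 0.05. Without liver TDB 1, 89 were higher and 5 lower. Tgtp1, Gbp2, Igtp and Tap1 passed in each of 19 alternatives, with adjusted p of at most 0.028, 0.03, 0.016 and 0.029. Other named calls ended without single libraries: the adjusted p without liver vehicle 1, 2 and 3 was 0.12, 0.17 and 0.14 for Cxcl9, 0.16, 0.058 and 0.17 for Ifit1, 0.25, 0.11 and 0.23 for Rtp4, 0.16, 0.11 and 0.12 for Psmb9, and 0.14, 0.2 and 0.27 for Cd8a. For Cxcl10 it was 0.065 and 0.078 without liver vehicle 1 and 2. Without liver TDB 2 it was 0.095 for Ifit1, 0.16 for Rtp4, 0.078 for Psmb9, 0.16 for Cd8a, 0.16 for Marco, 0.26 for Junb, 0.29 for Lpl, 0.18 for Spc25 and 0.31 for Alas1. Marco, Junb, Lpl, Spc25 and Alas1 also missed the threshold without each vehicle library (adjusted p from 0.18 for Spc25 to 0.36 for Lpl), and Junb, Spc25 and Alas1 without liver TDB 1 (0.071, 0.079 and 0.062).

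**Figure D1:**
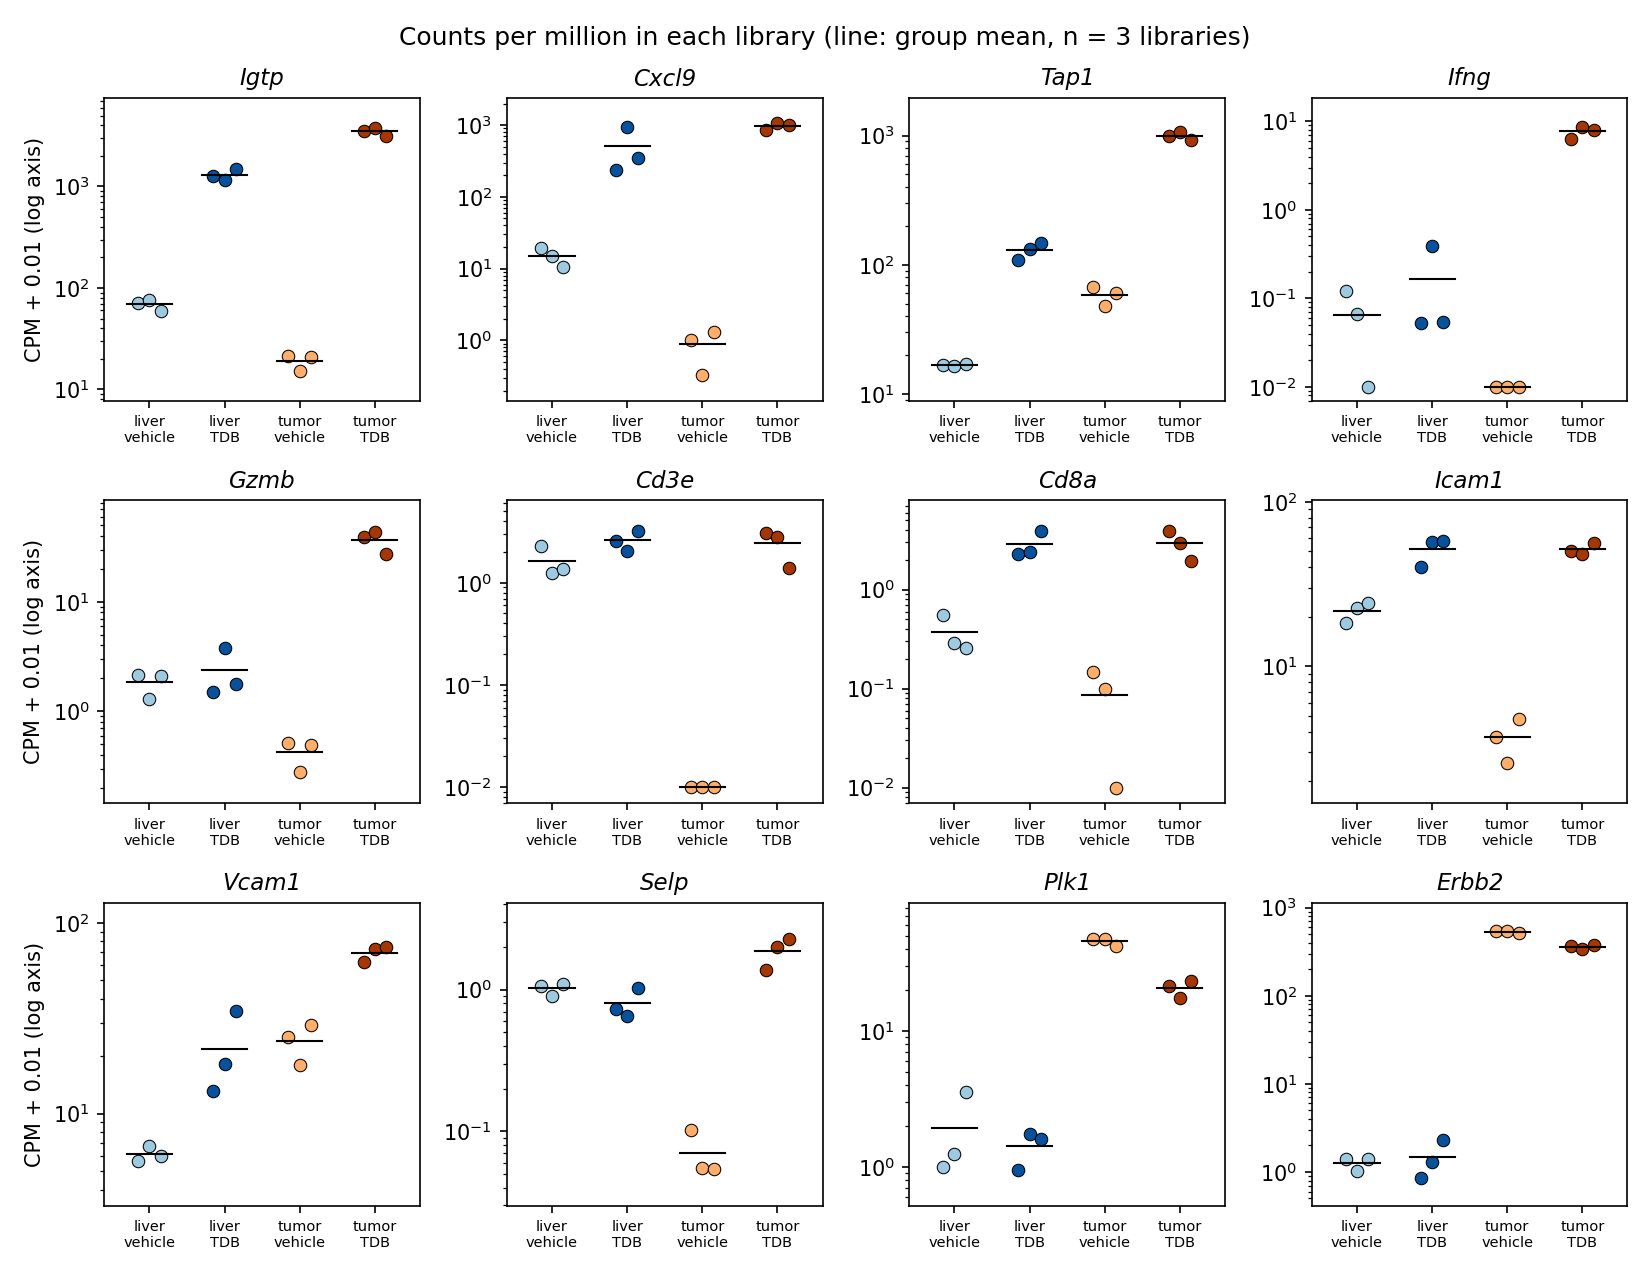
CPM (log axis, 0.01 added) of 12 genes in each of the 12 libraries, with a line at each group's mean. In tumor the vehicle libraries hold 0 counts of Ifng and Cd3e, and in liver Cd8a lies at 0.36 CPM with vehicle and at 2.86 CPM with TDB on average.

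The second comparison asked which genes differed between the groups in the tumor, the tissue that carries the HER2 transgene. Interferon-gamma and its response genes, T cell and cytotoxic genes and antigen presentation genes rose, and proliferation genes fell. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892) had 0 counts in the vehicle libraries and 7.7 ± 1.21 CPM with TDB, at least 158-fold higher (adjusted p = 1.3e-05). Plk1, a mitotic kinase (ENSMUSG00000030867, chromosome 7, 122159439 to 122169873), went from 45.6 ± 3.36 to 20.6 ± 2.94 CPM, a log2 fold change of -1.15 (SE 0.12, adjusted p = 0.00014). In total 2437 genes were higher and 2019 lower among 15454 tested, by edgeR's quasi-likelihood test, of which 1122 and 444 changed at least 2-fold. Higher genes made up 54.7% of these calls, against 55.8% with median-of-ratios size factors, 41% with upper quartile scaling, and 45.1% and 44.7% by limma-trend on the deposited FPKM values with 1 and 0.1 added, which changes the test as well.

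All 23 measured members of the interferon-gamma response list rose, with a median log2 fold change of 7.5, or 7.15 with the 3 members without vehicle counts at their lower bound (adjusted p = 7.6e-29, and adjusted p = 0.019 with an estimated correlation). Ubd, a ubiquitin-like modifier, had 0 counts with vehicle and 41.8 ± 13.5 CPM with TDB, at least 879-fold higher. Gbp4 went from 0.812 ± 0.306 to 1270 ± 152 CPM and Tgtp1 from 0.134 ± 0.0877 to 243 ± 15.1 CPM, with the same uncertainty between family members as in liver. Cxcl9 went from 0.868 ± 0.497 to 968 ± 106 CPM and Cxcl10 from 1.33 ± 0.942 to 121 ± 4.91 CPM. Pdcd1lg2, the PD-1 ligand PD-L2, had 0 counts with vehicle and 13.7 ± 4.96 CPM with TDB, at least 284-fold higher.

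All 20 type I interferon-stimulated genes rose (median 3.62, adjusted p = 4.1e-19, and adjusted p = 0.063 with an estimated correlation), as did all 14 MHC class I (median 3, adjusted p = 4.1e-19, and adjusted p = 0.044 with an estimated correlation) and all 10 measured MHC class II genes (median 3.91, adjusted p = 1.3e-09, and adjusted p = 0.098 with an estimated correlation). These counts were the same adjusted over the list alone. Oas2, an antiviral enzyme, rose by 5.33 (SE 0.13), Nlrc5, the class I transactivator, by 7.15 (SE 0.16) and Ciita, its class II counterpart, by 5.58 (SE 0.2).

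Of 18 measured T cell activation and cytotoxicity genes, 17 rose, and adjusted over the list alone 17 rose and 1 fell (median 5.16, adjusted p = 2.2e-12, and adjusted p = 0.063 with an estimated correlation). Gzmb went from 0.42 ± 0.129 to 36.5 ± 8.48 CPM, a log2 fold change of 6.43 (SE 0.27). Prf1, the pore-forming perforin, had 2 counts with vehicle and 684 with TDB, a count ratio of 299 with a counting interval of 82.4 to 2470. Of 18 T cell markers, 16 rose, by both adjustments (median 4.12, adjusted p = 4.7e-10, and adjusted p = 0.22 with an estimated correlation). Cd3e had 0 counts with vehicle and 2.41 ± 0.912 CPM with TDB, at least 49.8-fold higher, and Cd8a went from 0.0759 ± 0.0698 to 2.94 ± 0.979 CPM. Cd4 was at 2.43 ± 0.973 and 3.42 ± 0.195 CPM (log2 fold change 0.49, SE 0.3, adjusted p = 0.25). All 5 measured NK cell markers rose (median 4.97, adjusted p = 3.2e-05, and adjusted p = 0.11 with an estimated correlation), among them Klrk1, the NKG2D receptor that T cells carry as well (6.55, SE 0.48). Of 14 lymphocyte homing receptors 11 rose, and 13 adjusted over the list alone (median 2.46, adjusted p = 4.1e-08, and adjusted p = 0.11 with an estimated correlation).

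Myeloid lists shifted up as well. Of 17 monocyte and macrophage markers 13 rose, and 15 adjusted over the list alone (median 1.21, adjusted p = 7.1e-09, and adjusted p = 0.12 with an estimated correlation), including the Fc receptor Fcgr4 (4.09, SE 0.21). Of 8 dendritic cell markers 6 rose (median 3.47, adjusted p = 0.00079, and adjusted p = 0.11 with an estimated correlation). Clec9a was among them, with 0 counts with vehicle and 1.68 ± 0.634 CPM with TDB, at least 33.2-fold higher. Of 8 neutrophil markers 5 rose (median 2.02, adjusted p = 0.005, and adjusted p = 0.41 with an estimated correlation). Adjusted over the list alone, these 6 and 5 were the same in number. Both measured B cell markers rose (median 1.67), and of 4 measured Kupffer cell markers 1 rose and 2 fell (median -0.63, mean 0.57); both lists were too short to test.

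Inflammatory cytokines and NF-kB targets rose in 19 of 22 cases (median 1.48, adjusted p = 3e-10, and adjusted p = 0.2 with an estimated correlation), with Tnf at 3.26 (SE 0.22). Of 19 chemokines outside the interferon-gamma list 11 rose (median 2.05, adjusted p = 4.2e-06, and adjusted p = 0.26 with an estimated correlation), with the T cell attractant Ccl5 at 5.39 (SE 0.23). Adjusted over the list alone, 19 and 11 of them rose. Of 20 acute-phase genes 11 rose, and adjusted over the list alone 13 rose and 1 fell (median 1.42, adjusted p = 0.00079, and adjusted p = 0.26 with an estimated correlation). The complement gene C3 went from 6.08 ± 3.41 to 284 ± 46.2 CPM, and Saa1 rose by 3.18 (SE 0.42, adjusted p = 0.004 and up to 0.22 over the alternatives). Of 18 p53 targets and apoptosis genes 8 rose, and adjusted over the list alone 8 rose and 1 fell (median 0.22, adjusted p = 0.0015, and adjusted p = 0.26 with an estimated correlation). They included the executioners of lytic cell death Gsdmd (2.61, SE 0.2) and Mlkl (2.13, SE 0.09). Immediate early and heat shock genes had 5 higher and 3 lower of 18, and 6 and 3 adjusted over the list alone (median 0.13, adjusted p = 0.21).

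Genes linked to vessels went both ways, and bulk libraries do not show which cells carried these changes. Of 11 endothelial adhesion molecules 4 rose and 2 fell, by both adjustments (median 0.29, adjusted p = 0.073). Icam1 went from 3.68 ± 1.1 to 51.6 ± 4.23 CPM, Vcam1 from 24 ± 5.65 to 69.7 ± 6.65 CPM and Selp, P-selectin, from 0.0603 ± 0.0271 to 1.86 ± 0.45 CPM, all past the threshold, and the junction molecule Jam2 fell by 0.97 on the log2 scale (SE 0.12). Pecam1 had a log2 fold change of 0.16 (SE 0.2, adjusted p = 0.6), and Sele, with 4 counts in each group, was too low to test. Of 18 pan-endothelial markers 4 fell, by both adjustments, including the VEGF receptor Kdr (-0.94, SE 0.16). The list's median was -0.29 (adjusted p = 0.031, and adjusted p = 0.7 with an estimated correlation), a call held in 10 of 21 alternatives (adjusted p from 0.00046 to 0.7) and lost, among others, without tumor vehicle 3 (0.16), tumor TDB 1 (0.15) or tumor TDB 2 (0.051). Of 14 angiogenesis and tip endothelium genes 4 fell, by both adjustments (median -0.2, adjusted p = 0.015, and adjusted p = 0.48 with an estimated correlation), a call held in 18 of 21 alternatives (0.00076 to 0.48) and lost, among others, without tumor vehicle 3 (0.21). The apelin receptor Aplnr fell by 2.08 (SE 0.38). Ednrb, the endothelin receptor B, fell by 3.1 (SE 0.43) and Cd300lg, an adhesion receptor of endothelium, by 2.24 (SE 0.21), all on the log2 scale. Coagulation and endothelial hemostasis genes had 2 higher and 3 lower of 13, by both adjustments (median -0.06, mean 0.05, test directed up with adjusted p = 0.99). Of 8 liver sinusoidal endothelial markers 3 rose and 2 fell, with 4 and 2 adjusted over the list alone (median 0.72, adjusted p = 0.19), and Dnase1l3, a secreted DNase that dendritic cells make too, rose by 7.22 (SE 0.2).

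Of 20 proliferation genes 18 fell, and 20 adjusted over the list alone (median -1.08, adjusted p = 9.1e-11, and adjusted p = 0.26 with an estimated correlation), with the replication helicase subunit Mcm2 at -1.04 (SE 0.12). Among 17 mammary tumor epithelium markers 3 rose and 2 fell, by both adjustments (median 0.07, adjusted p = 0.83). Erbb2 went from 534 ± 15.9 to 358 ± 19.5 CPM (log2 fold change -0.58, SE 0.08, adjusted p = 0.00062, and up to 0.091 over the alternatives), and the whey protein gene Wap rose by 1.48 (SE 0.21). How reads of the human HER2 transgene were assigned relative to mouse Erbb2 is not given in the sources used here. The imprinted gene Mest fell by 2.78 (SE 0.22). Lipid and glucose metabolism genes had 1 higher and 6 lower of 18, and 2 and 8 adjusted over the list alone (median -0.22, adjusted p = 0.031, and adjusted p = 0.36 with an estimated correlation), a call held in 10 of 21 alternatives (adjusted p from 0.0013 to 0.36) and lost, among others, without tumor TDB 2 (0.051). Fibroblast, stellate cell and pericyte markers had 2 lower of 13, and 1 adjusted over the list alone (median -0.38, adjusted p = 0.084), with the pericyte gene Rgs5 at -1.32 (SE 0.15). That list passed without tumor vehicle 1 (0.036), tumor vehicle 2 (0.013) or tumor TDB 3 (0.029), with up to 0.7 over the alternatives. Cholangiocyte markers had 2 higher of 5 (median 0.28, adjusted p = 0.069, and 0.049 and 0.043 without tumor vehicle 1 and tumor TDB 3, and a range of 0.00075 to 0.47). By edgeR 0 of 7 hepatocyte markers passed, 0 by DESeq2 and limma-voom and 1 at an unadjusted p under 0.05 (median -0.32, adjusted p = 0.52). By the same 3 tools 0 of 5 erythroid markers passed, and 0 at an unadjusted p under 0.05 (median -0.11, mean 0.14, adjusted p = 0.99). Cytochrome P450 genes (4 measured, 1 higher and 1 lower, median -0.19, mean 0.09), adipocyte markers (3 measured, median 0.12) and skeletal muscle markers (3 measured, median -0.36) were too few for a list test, and Cyp7a1 had 0 counts in both tumor groups.

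Leaving out tumor TDB 2 left 1145 lower genes, the 1 change of a tumor count by over 1.5 times among the 6 libraries left out in turn. In tumor a first principal component with 79% of the variance parted the TDB libraries (51.4 to 64) from the vehicle libraries (-65.6 to -49.8).

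**Figure D2:**
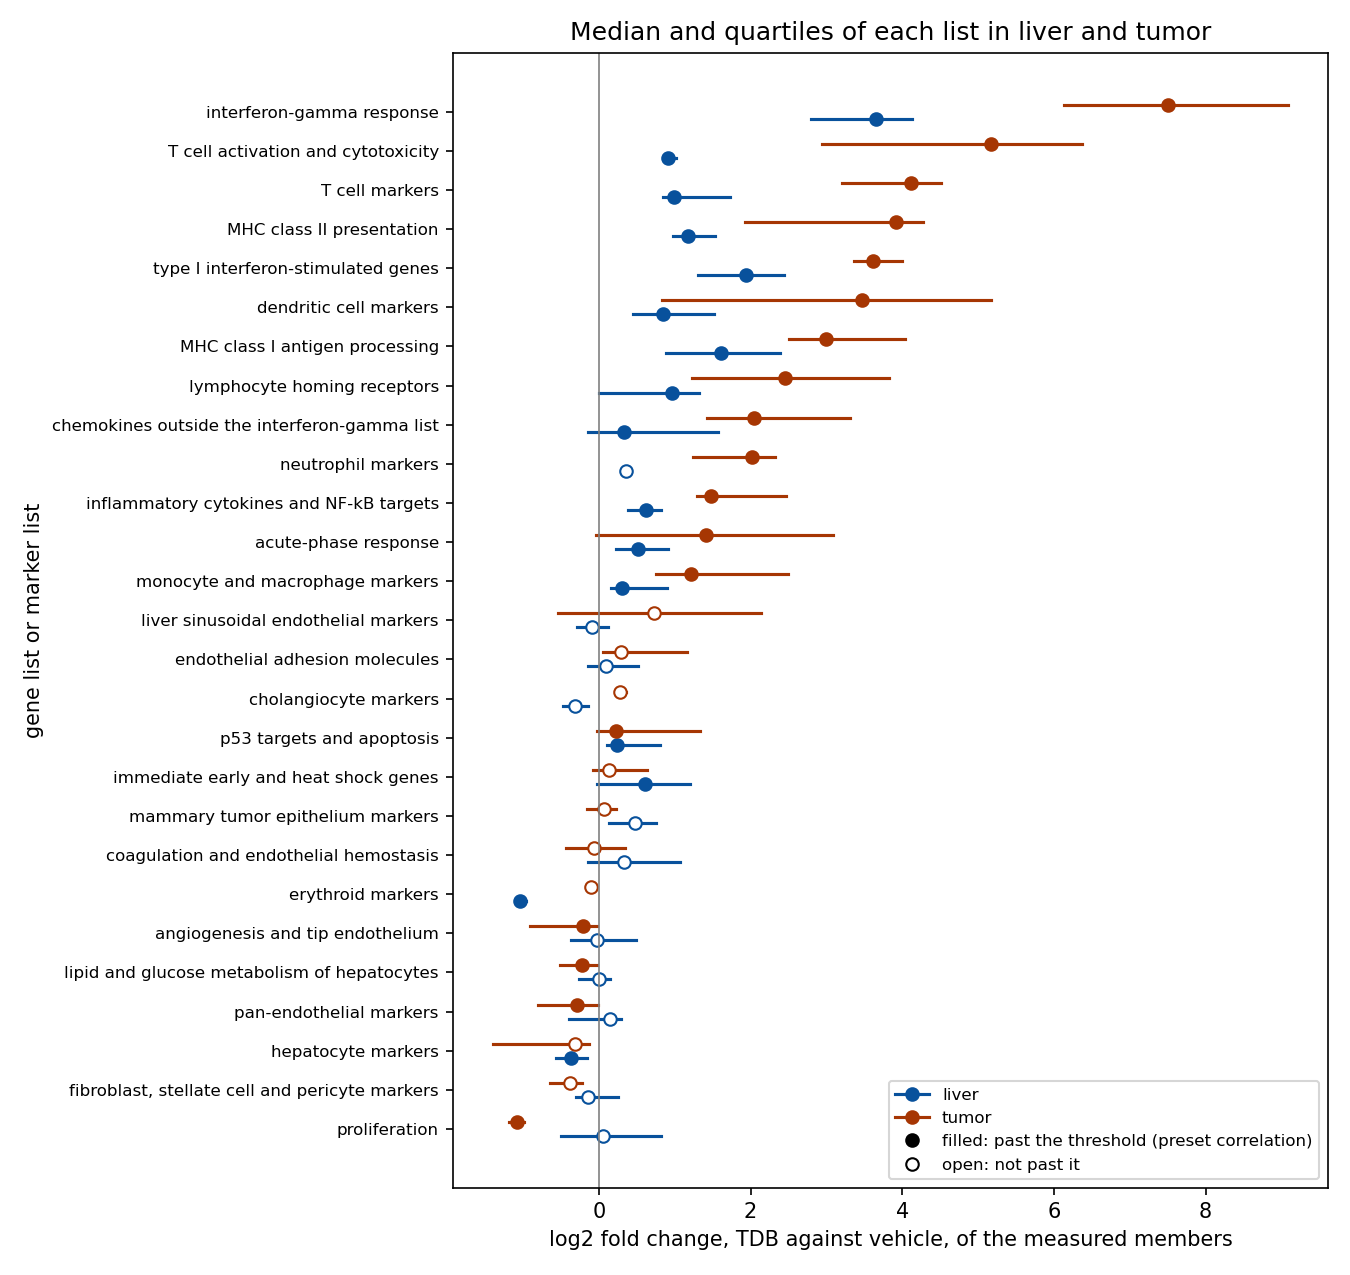
Median log2 fold change (horizontal axis) with quartiles of the gene and marker lists tested in both liver and tumor, filled where the list passed with a preset correlation. The interferon-gamma response list has medians of 3.66 in liver and 7.5 in tumor, and the proliferation list lies at 0.05 and -1.08.

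The series title concerns organ-specific change, so the difference between the TDB effects in the 2 tissues was tested itself. On the log2 scale, T cell, cytotoxic and interferon-gamma response genes rose more in tumor than in liver. For Cd3e the vehicle levels differed, with 0 counts in tumor libraries and 1.23 to 2.26 CPM in liver libraries. With TDB, Cd3e was at 1.37 to 3.06 CPM in tumor and 2.04 to 3.17 CPM in liver, each scaled within its tissue. The difference was 6.02 log2 units for Gzmb (SE 0.57, adjusted p = 0.00019), 6.91 for Gbp4 (SE 0.5, adjusted p = 4.8e-05) and 4.98 for Cxcl9 (SE 0.75, adjusted p = 0.0041). On levels scaled across both tissues, Cxcl9 was at 9.34 log2 CPM in liver and 9.25 in tumor with TDB. With vehicle it was at 4.52 and -0.75, so its difference came from the vehicle levels. Gbp4 reached 6.2 log2 CPM in liver and 9.65 in tumor with TDB. Pclaf and Uhrf1, which act at replicating DNA, had differences of -4.38 (SE 0.5) and -4.3 (SE 0.5), and Uhrf1 went from 0.267 ± 0.11 to 2.26 ± 0.811 CPM in liver and from 30.1 ± 2.83 to 13.2 ± 4.1 CPM in tumor. Of 16557 genes tested in all 12 libraries, 303 had a higher and 109 a lower TDB effect in tumor than in liver by edgeR's quasi-likelihood test. The counts were 557 and 509 by limma-trend on FPKM values with 1 added, and 450 and 269 with length and GC trends removed. With library numbers taken as mice across tissues, as a fixed block, they were 216 and 42. The median difference over all genes was -0.116 with TMM scaling and 0.002 on FPKM values with 1 added, and single differences are to be read relative to that shift.

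Of 23 interferon-gamma response genes 19 had a larger effect in tumor, and 21 adjusted over the list alone (median difference 3.22, adjusted p = 1.5e-43). For MHC class I genes it was 8 of 14, and 14 adjusted over the list alone (median 1.53, adjusted p = 6.5e-21), for MHC class II genes 6 of 11, and 8 (median 2.74, adjusted p = 2e-12), and for type I interferon-stimulated genes 6 of 20, and 15 (median 1.56, adjusted p = 6.5e-21). Of 18 T cell activation and cytotoxicity genes 6 had a larger effect in tumor, with 12 larger and 1 smaller adjusted over the list alone (median 3.68, adjusted p = 5.5e-15), and of 20 T cell markers 7, with 16 and 1 (median 2.34, adjusted p = 1.8e-15). On FPKM values with 1 added the T cell marker difference changed direction (adjusted p = 0.16, with 25 of 27 alternatives past the threshold and a lowest of 1.6e-21). With an estimated correlation these calls held, as did those of the lymphocyte homing receptors and of the NK cell, B cell, monocyte and macrophage and dendritic cell markers, 11 lists in total. Of 9 B cell markers 2 had a larger effect in tumor, and 8 adjusted over the list alone. Only 2 of the B cell markers were high enough to test within tumor, so most had low counts there. The dendritic cell median was 2.3, or 1.21 with its member without vehicle counts at its bound, and its call held in 25 of 27 alternatives (4.7e-07 to 0.6). Perforin (Prf1) had a difference of 7.02 (SE 0.73), Dnase1l3 one of 6.38 (SE 0.35), and Pigr, the carrier of secretory antibodies, one of 6.44 (SE 0.54), with 8.64 ± 1.41 and 887 ± 349 CPM in tumor against 1220 ± 380 and 1410 ± 494 CPM in liver. Ubd and Cd3e, without counts in tumor vehicle libraries, had fitted differences of 9.56 and 7.6, which depend on the prior count and are no bounds.

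Chemokines outside the interferon-gamma list, inflammatory cytokines and NF-kB targets, proliferation genes, p53 targets, and neutrophil, hepatocyte and erythroid markers passed with the preset correlation and not with an estimated one. Cxcl10 had a difference of 2.66 (SE 0.63, adjusted p = 0.048), a call lost without each of liver vehicle 1, 2 and 3 (0.1, 0.072 and 0.11), liver TDB 1 and 2 (0.062 and 0.11), tumor vehicle 1 (0.093) and tumor TDB 1, 2 and 3 (0.1, 0.12 and 0.1), with a range of 0.0012 to 0.12 over the alternatives. Ifng had an adjusted p of 0.093, with 0.017 without liver TDB 2 and a range of 3.2e-05 to 0.43 over the alternatives. Of the adhesion molecules, Icam1 (2.51, SE 0.32) and Selp (5.11, SE 0.54) had larger effects in tumor, and Vcam1 did not differ past the threshold (-0.34, SE 0.42, adjusted p = 0.87). With TDB, Icam1 was at 48.12 to 56.33 CPM in tumor and 40.24 to 58.02 CPM in liver, each scaled within its tissue. With vehicle it was at 2.574 to 4.764 and 18.23 to 24.15 CPM. Jam2 had a lower effect in tumor (-1.64, adjusted p = 0.0068). Their list of 11 did not pass (camera adjusted p = 0.055) and passed in 8 of 27 alternatives (6.9e-08 to 0.46). Ednrb (-3.08, SE 0.53) and Aplnr (-4.15, SE 0.76) had lower effects in tumor. Aplnr fell by 2.08 within tumor and was too low to test within liver, so its difference rests in part on low liver counts. Cd8a (2.13, SE 0.82, adjusted p = 0.28), Cd4 (-0.49, SE 0.55), Pecam1 (-0.15, SE 0.31), Saa1 (3.79, SE 1.9, and -0.75 without liver vehicle 2) and Erbb2 (-0.84, SE 0.38, adjusted p = 0.39) did not pass.

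The count of larger effects in tumor was 525 without liver TDB 3 and 196 without tumor TDB 2. The count of smaller effects was 177 and 171 without liver TDB 1 and 3, 56 and 69 without liver vehicle 1 and liver TDB 2, 56, 54 and 72 without tumor vehicle 1, 2 and 3, and 51, 45 and 65 without tumor TDB 1, 2 and 3. Among the 12608 genes tested in both tissues, 68 rose in liver and 2062 in tumor, and 63 rose in both, where 11.1 are expected for independent lists (one-sided Fisher's exact test, p = 5.7e-44). That test, also used for lower genes, takes genes as independent units, so its p-value does not measure the spread between mice. The 1 gene called in opposite directions was Uhrf1, named here by the rule for the difference. Of genes lower in liver 2 were tested in both, 1657 were lower in tumor and 1 was shared (expected 0.263, one-sided Fisher's exact test, p = 0.25). The shared count of higher genes was 18, 14, 17 and 24 without liver vehicle 1, 2 and 3 and liver TDB 2, and 135 without liver TDB 3. Across these genes, which are not independent replicates, the log2 fold changes in liver and tumor had a Pearson r of 0.553 and a Spearman rho of 0.411.

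**Figure D3:**
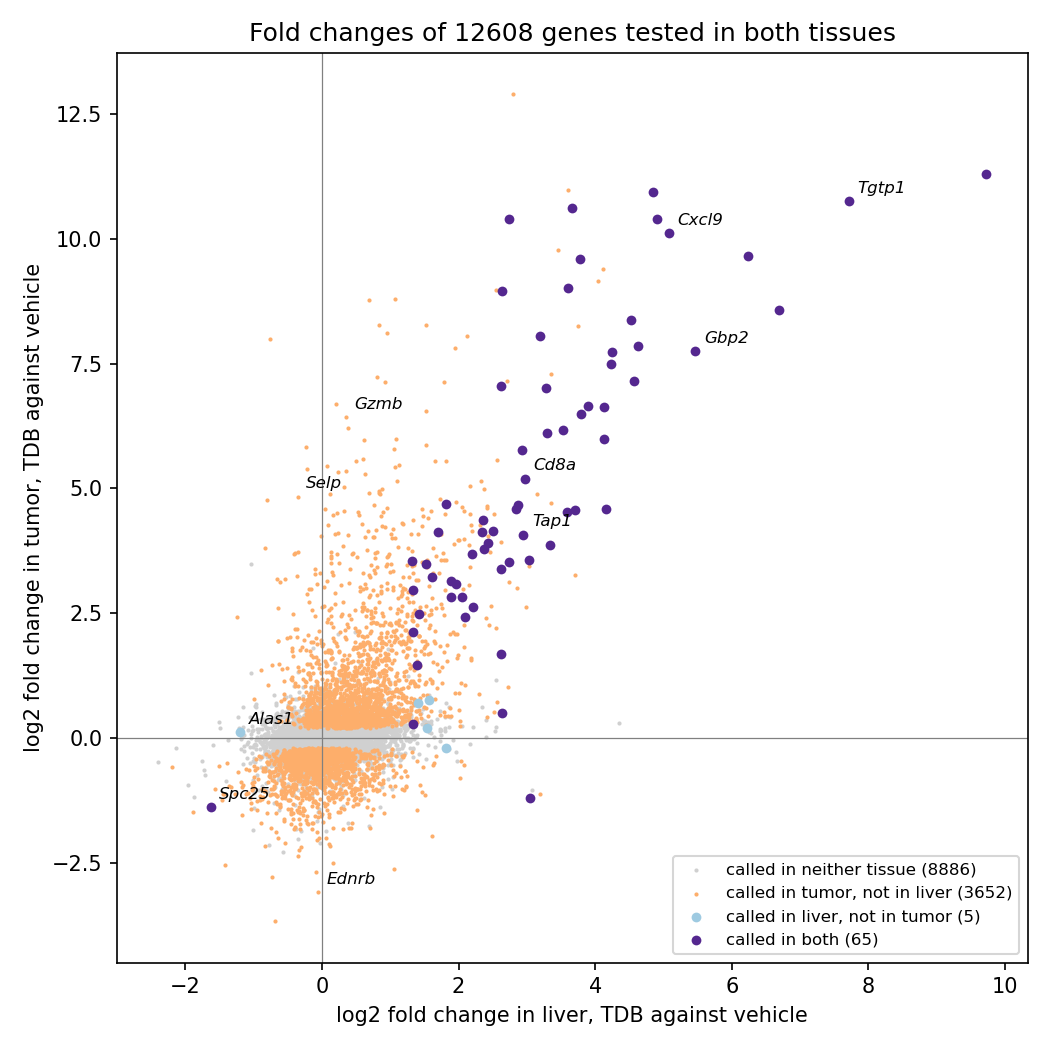
Log2 fold change with TDB in tumor (vertical axis) against liver (horizontal axis) for 12608 genes tested in both tissues, colored by the tissue in which a gene was called. The 63 genes higher in both lie in the upper right, and Pearson's r across genes is 0.553.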

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

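The splits of the libraries and the tests of explanations in this part were chosen only after the results were seen, and the interaction tests were planned. The results listed here are those in which the TDB effect differed between tumor and liver by the interaction test (edgeR, 12 libraries, 3 mice per group). Values are log2 effect in tumor minus log2 effect in liver.

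Among genes, the difference was 9.56 for Ubd and 7.6 for Cd3e, both fitted against tumor vehicle libraries without counts and therefore no bounds, and 7.02 for Prf1, with 2 counts in tumor vehicle libraries. It was 6.91 for Gbp4, 6.44 for Pigr, 6.38 for Dnase1l3, 6.02 for Gzmb, 5.55 for Ccl5, 5.11 for Selp, 5.06 for Oas2, 5.02 for C3, 4.98 for Cxcl9, 4.95 for Klrk1 and 4.41 for Nlrc5. For Igtp it was 3.22, for Tgtp1 2.97, for Ciita 2.97, for Cxcl10 2.66, for Fcgr4 2.64, for Tnf 2.52, for Icam1 2.51 and for Gbp2 2.24. Smaller differences were those of Gsdmd (1.79), Psmb9 (1.75), Rtp4 (1.44), Alas1 (1.27, with -1.19 in liver and 0.11 in tumor) and Tap1 (1.08). Differences below 0 were those of Jam2 (-1.64), Mcm2 (-1.92), Cd300lg (-1.95), Mest (-2.08), Ednrb (-3.08), Aplnr (-4.15, with -2.08 in tumor and too low to test within liver), Uhrf1 (-4.3, with 3.05 in liver and -1.2 in tumor) and Pclaf (-4.38, with 3.19 in liver and -1.13 in tumor). Adjusted p lay between 6.9e-06 (Dnase1l3) and 0.048 (Cxcl10, lost in 9 of 12 fits without 1 library, as the report gives with the values).

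Among lists, the median difference was 4.34 for NK cell markers, 3.68 for T cell activation and cytotoxicity, 3.22 for the interferon-gamma response, 2.74 for MHC class II presentation, 2.37 for B cell markers, 2.34 for T cell markers, 2.3 for dendritic cell markers, 1.56 for type I interferon-stimulated genes, 1.53 for MHC class I antigen processing, 1.09 for lymphocyte homing receptors and 0.94 for monocyte and macrophage markers. These 11 also passed with an estimated correlation. Of the 9 B cell markers measured only 2 were high enough to test within tumor. The dendritic cell median was 1.21 with its member without tumor vehicle counts at its bound. The other 7 lists did not pass with an estimated correlation. They were neutrophil markers (1.88, adjusted p = 3e-05, and adjusted p = 0.059 with an estimated correlation), chemokines outside the interferon-gamma list (1.5, adjusted p = 1.1e-06, and adjusted p = 0.085 with an estimated correlation), inflammatory cytokines and NF-kB targets (0.75, adjusted p = 8.1e-07, and adjusted p = 0.14 with an estimated correlation) and proliferation (-1.18, adjusted p = 3e-08, and adjusted p = 0.14 with an estimated correlation). The p53 targets and apoptosis list (0.06, adjusted p = 0.02, and adjusted p = 0.33 with an estimated correlation) lost its call without liver vehicle 2 (0.087), liver TDB 3 (0.079) or tumor vehicle 2 (0.068), with 0.0025 to 0.33 over the alternatives.

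Erythroid markers (0.91, adjusted p = 0.042, and adjusted p = 0.48 with an estimated correlation) passed in 5 of 26 alternatives (0.01 to 0.61). They missed the threshold without liver vehicle 2 (0.48) and 3 (0.073), liver TDB 2 (0.1) and 3 (0.51), tumor vehicle 1 (0.09) and 3 (0.3), and tumor TDB 1 (0.094), 2 (0.21) and 3 (0.068). Hepatocyte markers (-1.34, adjusted p = 0.04, and adjusted p = 0.54 with an estimated correlation) passed in 14 of 27 (8.6e-05 to 0.89). They missed it without liver vehicle 2 (0.087) and 3 (0.073), liver TDB 1 (0.11), and tumor TDB 2 (0.095) and 3 (0.069), and changed direction without tumor vehicle 2 (0.89). On FPKM values they passed in the opposite direction with 1 added, a call that the 14 include, and changed direction without a call with 0.1 added. Of 21 hepatocyte markers measured 7 were high enough to test within tumor.

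Within a tissue, 3 libraries against 3 make 10 splits, too few for a share under 0.05. Each other split also holds vehicle and TDB libraries on both sides. The TDB effect then widens its spread, so few calls there say little about chance. The real liver split gave 73 genes and 17 lists (1 of 10 splits as large for each) and the highest other split 0 genes and 13 lists, and the real tumor split gave 4456 genes and 19 lists and the highest other 0 genes and 16 lists. For the difference between tissues, 6 of 100 drawn splits gave as many genes as the real 412 (highest other 881). All 6 were among the 11 that kept the real tumor grouping and with it the TDB effect in tumor, and the 89 with another tumor grouping had at most 0 genes by edgeR, so these splits do not decide on chance for that count. As many lists as the real 18 came from 25 of 100 splits (highest other 23), 15 of them among the 89 with another tumor grouping (up to 22), so chance is not excluded for the count of lists. For the genes shared by liver and tumor 1 of 100 splits, the real one, was as large and the highest other had 0. As no other split of either tissue called a gene by edgeR, that count was fixed at 0 for the others, and these splits decide nothing about the overlap.

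Far fewer genes passed in liver (73) than in tumor (4456). With one spread fitted to all 12 libraries tumor still had 5.02 times the calls of liver (1681 and 335), against the wider spread of liver as the whole cause. A trend on transcript length and GC content is a candidate source of that spread: it took 37.2% of the within-group variance in liver, against 2.3% in tumor and at most 0.181% in 100 permutations. It is not the whole source, since the biological coefficient of variation was 23.5% in liver after its removal, against 12.5% in tumor. A smaller response of liver stays open as a biological explanation, as do technical differences between liver samples that no label records.

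The interferon-gamma response list rose more in tumor than in liver. On levels scaled by TMM across both tissues, unlike the CPM values of the report, vehicle levels were lower in tumor (median log2 difference from liver -1.63), but with TDB the members lay above liver by a median of 1.42 (quartiles 0.11 to 2.66, 18 of 23 higher), against a higher level in untreated liver as the whole cause. Under 3 other scalings the lower quartile was 0.16 to 1.25. With TMM, Cxcl9 (-0.08) and Tgtp1 (-0.41) were among the members not higher, and Igtp (0.17) and Cxcl10 (0.08) lay close to liver. After removal of the length and GC trend the median difference was 3.08, with 19 of 23 members past the threshold, against that trend as the whole cause. Binding of the antibody to the tumor, and local T cell activation there, may explain the pattern and were not tested.

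Ednrb, Cd300lg and Aplnr fell in tumor by over 2 log2 units (the least lowered at -2.08). Pan-endothelial markers had a median of -0.29 (lower quartile -0.81), against fewer endothelial cells as the whole cause, and mammary tumor epithelium markers one of 0.07 (lower quartile -0.16), against dilution by RNA of other cells. The capillary endothelium list was written after 5 of its 12 measured genes, Cd300lg, Btnl9, Ramp3, Aplnr and Ednrb, had been seen among the lowest in tumor. Its median was -1.03 and its lower quartile -2.17, with Btnl9 at -2.54 and Ramp3 at -2.14. These values rest in part on the 5 genes seen beforehand, so they do not decide on a loss of capillary endothelium. The members outside those 5 were Sema3g (-1.05), Gpihbp1 (-1.02), Kdr (-0.94), Fabp4 (0.12), Rgcc (0.45), Cd36 (0.6) and Car4. Car4 had 8.73, fitted against vehicle libraries without counts. All of them lay above -2.08, which argues against that loss as the whole cause, for the members covered. A partial loss, and lower expression of Ednrb, Cd300lg and Aplnr per endothelial cell, stay open.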

How the results depend on the processing

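The removal of length and GC trends, alone or with a block or without liver TDB 3, was chosen only after the results were seen, and the other alternatives were planned. Unless a cause is named, the cause was not tested.

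Of 687 list results in liver under the alternatives, 610 kept direction and side of the threshold, 31 lost and 24 gained a call, 22 changed sign without a call and 0 reversed. In tumor it was 530, 42, 25, 17 and 0 of 614, and for the difference between tissues 740, 50, 58, 14 and 4 of 866. Of 672 results of 32 named liver genes, 530 kept both, 71 lost and 62 gained a call, and 9 genes kept both throughout. Of the 71 lost calls 10 were lost at an adjusted p under 0.01, a change of the threshold alone. Of 800 results of 40 tumor genes 793 kept both (35 genes throughout), and of 572 results of 22 genes for the difference 537 did (9 genes throughout). The totals in this paragraph include the alternatives that change only the threshold.

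In liver 70 genes were higher and 3 lower. The counts were 133 and 12 with no filter, 292 and 60 with DESeq2 (which held all 73 genes), 25 and 1 on FPKM values with 1 added, 290 and 45 with one fit of all 12 libraries, whose spread is shared with tumor, and 20 and 0 at an adjusted p under 0.01, a stricter threshold. With upper quartile scaling 5 were lower. With length and GC trends removed they were 214 and 26 (72 of the 73 genes among them), and 258 and 46 also without liver TDB 3. Without 1 library, 14 to 151 were higher and 0 to 12 lower (0 by edgeR without liver vehicle 1, 2 or 3 or liver TDB 2, with the report's counts at unadjusted p). With an estimated correlation 2 lists passed instead of 17.

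In tumor 2437 were higher and 2019 lower. With one fit of all 12 libraries, which brings in the wider spread of liver, 1055 and 626 passed. At least 2-fold changes were 1122 and 444, and 1607 and 930 passed at an adjusted p under 0.01. Without 1 library, 1797 to 2717 were higher and 1145 (without tumor TDB 2) to 2143 lower. With an estimated correlation 2 lists passed instead of 19.

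For the difference between tissues, 303 were higher and 109 lower in tumor. The counts were 577 and 315 with DESeq2, 557 and 509 on FPKM values with 1 added, 484 and 293 with 0.1 added, and 151 and 30 at an adjusted p under 0.01. With length and GC trends removed 269 were lower, and also without liver TDB 3 687 were higher and 265 lower. Without 1 library, 196 to 525 were higher and 45 to 177 lower. With an estimated correlation 11 lists passed instead of 18. T cell markers changed direction on FPKM values with 1 added (adjusted p = 0.16, with 25 of 27 alternatives past the threshold and a lowest of 1.6e-21), a scale that understates changes of low genes. Hepatocyte markers did so with 1 added (0.0049), with 0.1 added (0.07) and without tumor vehicle 2 (0.89), with 8.6e-05 to 0.89 over the alternatives.

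The number of genes higher in both tissues, 63, was 20 at an adjusted p under 0.01, 243 with DESeq2, 189 with length and GC trends removed and 14 to 135 without 1 library. The number lower in both, 1, was 0, 10, 7 and 0 to 2 under these alternatives.

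No label says that a library number marks one mouse across tissues. Within a tissue a number cannot mark one mouse, since vehicle and TDB libraries come from different mice. With a block by number, which there pairs no mice, liver had 291 higher and 59 lower genes, and 516 and 181 with length and GC trends removed as well. Same-number liver libraries correlated at -0.09, 0.46 and 0.61 in their deviations, and liver vehicle 2 with liver TDB 1 at 0.52, so liver libraries did not each correlate best with their own number. With mouse as a fixed block across tissues 216 genes were higher and 42 lower for the difference, and with mouse as a random block 396 and 144 (consensus correlation 0.042).

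Depth limits genes with few counts: Ifng had 3 counts in liver vehicle libraries, and Sele 4 in each tumor group.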

Other observations

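The 6 lists given here were written only after the results were seen, and their calls describe the same data.

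Complement components rose in tumor in 10 of 13 measured cases (median log2 fold change 1.54, camera adjusted p = 4.7e-06, and p = 0.077 with an estimated correlation), with C3 at 5.54 (SE 0.41), Cfb at 5.34 (SE 0.45) and C4b at 4.29 (SE 0.4). In liver the median was 0.31 over 19 genes (adjusted p = 0.041, and p = 0.19 with an estimated correlation). The difference between tissues was past the threshold for 6 of 19 (median 0.75, adjusted p = 1.1e-09, and p = 0.0012 with an estimated correlation).

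Of 15 glycolysis genes 3 rose in liver, Hk3 (2.36, SE 0.34), Pfkp (1.82, SE 0.29) and Pkm (1.54, SE 0.24), with adjusted p = 0.0023 for the list and p = 0.014 with an estimated correlation. In tumor 2 rose and 2 fell (adjusted p = 0.46), and the median difference between tissues was -0.38 (adjusted p = 0.0041, and p = 0.038 with an estimated correlation). Of the 15, 1 had a larger effect in tumor, Hk3 (difference 1.96, SE 0.42), which rose there by 4.36 (SE 0.21). The 2 with a smaller effect were Pfkp (-2.07, SE 0.29) and Pkm (-1.39, SE 0.22).

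The unfolded protein response list shifted up in liver (median 0.6 over 20 genes, adjusted p = 8.9e-07, and p = 0.082 with an estimated correlation), and in tumor 6 rose and 1 fell (median 0.2, adjusted p = 0.021, and p = 0.6 with an estimated correlation). The median difference between tissues was -0.36 (adjusted p = 0.0041, and p = 0.19 with an estimated correlation).

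The capillary endothelium list was written after 5 of its 12 genes had been seen among the lowest in tumor, so its tests in tumor and between tissues are not given. Of the 12, 7 fell and 2 rose in tumor. Btnl9 (-2.54, SE 0.26) and Ramp3 (-2.14, SE 0.25) are 2 of those 5, and Car4, which rose, had 0 counts in vehicle libraries and 2.29 CPM with TDB. In liver the list's median was -0.33 over 7 genes (adjusted p = 0.0093, and p = 0.051 with an estimated correlation).

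The last 2 lists, venous endothelium (adjusted p = 0.84 in liver, 0.99 in tumor and 0.37 for the difference) and short transcripts of oxidative phosphorylation (0.0051 and down in liver, with p = 0.47 with an estimated correlation, 0.27 in tumor and 0.085 for the difference), had medians of 0 and -0.31 in liver and -0.41 and -0.08 in tumor. Liver TDB 3 has deviations that correlate with transcript length (Spearman 0.7 across genes), and length and GC content take 51.5% of their variance.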
